A study of Mus musculus with 20 samples.

How the data were processed

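RNA was sequenced from 20 libraries of mouse bone marrow-derived macrophages, each measured for all genes at once. The cells came from wild-type C57BL/6 mice and were grown in RPMI with macrophage colony-stimulating factor. They were stimulated with lipopolysaccharide (LPS) and interferon gamma (IFNg), and samples were taken at 0, 1, 2, 4 and 6 h. Dimethyl itaconate (DI), a cell-permeable ester of the metabolite itaconate, was given at 250 µM for 12 h before the stimulus in 10 libraries, and the other 10 are controls (Ctrl). There are 10 groups of 2 libraries each.

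Per the labels' protocols, the libraries were made from poly(A) RNA with a barcoded oligo-dT primer, which reads the 3' ends of transcripts. Samples were pooled after first-strand synthesis in proportion to Actb measured by qPCR, and the pool was amplified for 12 cycles of PCR into strand-specific libraries. No molecular identifiers are named in the labels. The submitters' processing notes name STAR, HTSeq, DESeq2 and the mm10 genome build, without versions or options. The deposited table holds raw counts per Ensembl gene, 1 column per library, with no normalization applied by the authors. It holds 22165 genes, of which 21745 matched a symbol in the GENCODE M21 annotation of GRCm38, and each of its columns was matched to 1 library by name. Everything below was computed from these counts.

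Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr by group, which left 10663 genes, and libraries were scaled with trimmed means of M values (TMM). A single quasi-likelihood model with 1 coefficient per group was fitted to all 20 libraries with edgeR (glmQLFit, robust), so that the groups share their estimate of spread. The contrasts were DI against Ctrl at each of 5 times, each of 4 stimulated times against 0 h within Ctrl and within DI, and at each stimulated time the DI response minus the Ctrl response, which is called the response difference. Genes were called at an adjusted p under 0.05, with Benjamini-Hochberg adjustment within each contrast and no limit on fold change. Log2 fold changes are given with a standard error computed from the F statistic. Levels are counts scaled to library size with TMM factors (CPM), given as mean ± SD of the 2 libraries of a group. Summed levels of marker lists are the exception, scaled to the total of all genes in the library without TMM factors.

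Fixed gene lists were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The treatment contrasts make 95 list tests and the response differences 76, and p was adjusted within each family. Lists with fewer than 3 measured members were given as levels only. Induced and repressed classes were defined in Ctrl from the 1 h and the 6 h libraries, or from the 1 h and the 4 h libraries for the test at 6 h, at an adjusted p under 0.05 and a log2 fold change of at least 1. The tested contrast therefore shares no library with the class definition.

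The contrasts, the tests, the lists, the classes, the alternatives other than the 5 added later and the rule for named genes were chosen before the data were examined. The rule names, per contrast, up to 8 genes with the largest rise and 8 with the largest fall among called genes of at least 20 CPM in the higher group whose libraries do not overlap between groups. For a response difference the condition on overlap does not apply. It adds a fixed panel of cytokine, regulator, enzyme, interferon-response, NRF2-target and reference genes, and up to 4 members of each list with the smallest p, and leaves out predicted genes. The panel is not given in full: its members Atf3 and Ccl5 have no values below, and several others are given at some times only. Genes named outside it are said to be chosen after their values were seen.

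The alternatives fixed in advance were size factors of DESeq2 in place of TMM, no filter on low counts, a filter of at least 5 CPM in 2 libraries, limma-voom, the DESeq2 Wald test, a model of the compared groups alone, a replicate block and leaving out each library in turn. For the lists and classes they were the estimated correlation and a class limit of 2 on the log2 scale. After the data were seen 5 more were added. They are counts collapsed to estimated molecules, quality weights by treatment in limma-voom, a refit of genes with a mean of at least 32 CPM, the TMM factors of those genes applied to all genes, and a fit without replicate 2 of DI at 2, 4 and 6 h, the 3 libraries with the most genes at 0. Reads per molecule were estimated for each library from genes with between 4 and about 12 expected reads, by the share of them at 0.

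The steps were tested on simulated counts with 200 changed genes of at least 5 CPM, drawn from the means of the real libraries with dispersions per molecule of 0.03 for Ctrl and 0.05 for DI and the reads per molecule of each library. For DI against Ctrl at 4 h the test recovered 31 of 50 genes set 4-fold higher, 25 of 50 set 4-fold lower, 2 of 50 set 2-fold higher and 6 of 50 set 2-fold lower. Of 10360 unchanged genes it called 1 higher and 24 lower, and 7.82% had an unadjusted p under 0.05. For Ctrl at 4 h against 0 h that share was 0.704%, with 0 unchanged genes called and 32 of 50 genes set 4-fold higher recovered. In these simulations p thus ran too small for DI against Ctrl and too large within Ctrl. Calls of DI against Ctrl can therefore hold more false calls than the threshold states. For the response difference at 4 h it recovered 4 of 50 genes set 4-fold higher and 11 of 50 set 4-fold lower. On these simulated counts camera gave the changed list a p of 5.85e-30 for DI against Ctrl at 4 h, and 0 of 20 unchanged lists passed 0.05. For the response difference at 4 h the changed list had a p of 1.70e-17 and 2 of 20 unchanged lists passed 0.05. Simulated genes were drawn independently of each other, so these list tests do not show how camera deals with correlated genes.

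Total counts per library ran from 3655977 to 8938983. A floor of 3 counts, the most that a count of 0 allows at 95%, is 0.336 to 0.821 CPM. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. At the 7.75 to 11.9 reads per molecule estimated in DI, levels of a few CPM in DI rest on few molecules. Fold changes from such levels are imprecise, and the floor of 3 counts and the bounds from it are too low there. The labels do not say whether the 2 replicates of a group are separate cultures or animals, so p-values measure only the spread between these samples. The 420 gene identifiers with no symbol were tested but are not named.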

Results

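Transcript counts were measured in bone marrow-derived macrophages of C57BL/6 mice, in 10 groups of 2 libraries. Ctrl cells and cells given DI for 12 h were sampled before a stimulus of LPS and IFNg (0 h) and 1, 2, 4 and 6 h after it. LPS is a bacterial cell wall component that signals through TLR4, and IFNg is a cytokine that together with it drives inflammatory activation of macrophages. Total counts ran from 3655977 to 8938983 in Ctrl libraries and from 3982073 to 6725447 in DI libraries, and the 50 most abundant genes took 19.4 to 30.6% and 22.9 to 30.8% of them. Transcripts of the mitochondrial genome took 1.22 to 1.81% in Ctrl and 1.22 to 2.21% in DI.

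The DI libraries were less complex than the Ctrl libraries. They held 333 to 674 genes with 1 to 3 reads against 1370 to 1741 in Ctrl, although their totals were similar. Genes at 0 numbered 11143 to 12356 in DI and 9301 to 10859 in Ctrl. Of genes with 4 to about 12 expected reads, 20.8 to 40.4% were at 0 in DI libraries and 2.56 to 6.85% in Ctrl. The estimate of reads per molecule was 7.75 to 11.9 in DI and 2.34 to 3.42 in Ctrl, which gives a median of 552160 molecules per DI library and 1998500 per Ctrl library. Ctrl reads thinned to that number for DI had 38.9 to 39.1% of a set of 1841 genes at 0 against 23.9% in DI, and 1020000 molecules matched DI, so the estimate for DI is low by this measure. The coefficient of variation between replicates was 43.8% in DI and 20.2% in Ctrl on reads, and 22.8 and 17.1% on estimated molecules. Replicate 2 of DI at 2, 4 and 6 h had the most genes at 0 (12019, 12328 and 12356), and that at 4 h lay at −86.0 on the fourth principal component (6.12% of the variance) against 1.06 for replicate 1.

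**Figure D1:**
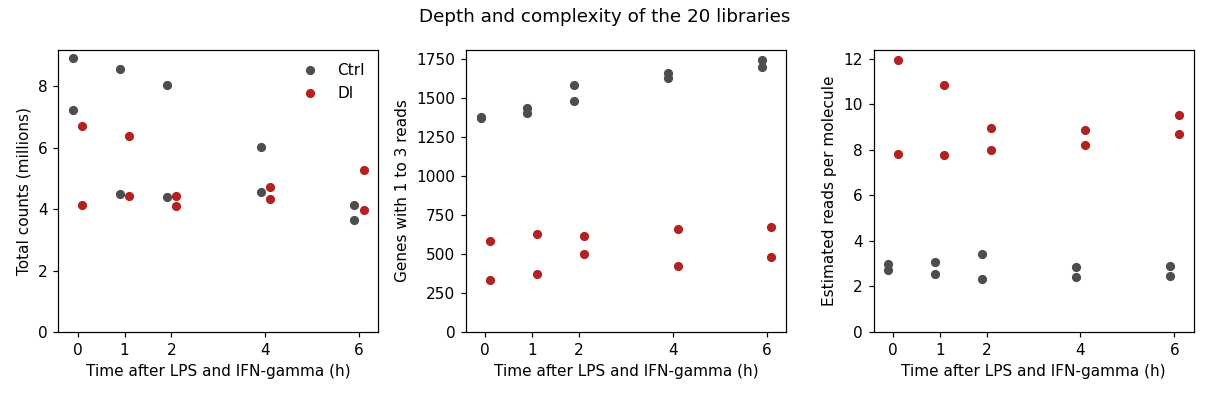
Total counts, genes with 1 to 3 reads and estimated reads per molecule in each of the 20 libraries, by time after the stimulus in h, with 1 point per library and Ctrl and DI in separate colours. All 10 DI libraries lie below the Ctrl libraries in genes with 1 to 3 reads (333 to 674 against 1370 to 1741).

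The first comparison asks how Ctrl macrophages responded to LPS and IFNg. Within 1 h 28 of 32 NF-kB primary response genes rose. Cxcl2, a neutrophil-attracting chemokine, went from 11.3 ± 2.52 to 7386 ± 716 CPM (n = 2 per group), a log2 fold change of 9.35 ± 0.41. The cytokine gene Tnf rose by 5.87 ± 0.32, the growth-response factor Egr1 by 7.12 ± 0.42, and Nfkbiz, which encodes the nuclear NF-kB cofactor IkBz, by 6.13 ± 0.32. By 4 h the cytokine genes Il6 and Il12b had risen by 9.60 ± 0.54 and 9.50 ± 0.56, and Ptgs2, the inducible cyclooxygenase, had reached 7741 ± 1208 CPM from 5.65 ± 0.416. At 6 h Nos2, the inducible nitric oxide synthase, was up by 8.57 ± 0.56 and Acod1, the enzyme that makes itaconate, by 7.04 ± 0.38.

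Several fixed lists rose in Ctrl. Of the 32 NF-kB primary response genes 28 rose at 1 h, 31 at 2 h, 30 at 4 h and 30 at 6 h, with 1 lower at that time. Immediate-early genes rose in 13 of 17 at 1 h, and in 10 at 6 h with 3 fallen. The IkBz-dependent secondary genes rose in 3, 7, 9 and 9 of 9 at the 4 times. Type I interferon-stimulated genes rose in 13, 20, 29 and 32 of 32, among them Cxcl10 (7.44 ± 0.32 at 4 h) and Rsad2 (3.75 ± 0.27), which encodes the antiviral protein viperin. IFNg-induced GTPases and regulators rose in 13 and 20 of 20 at 1 and 6 h. MHC class I presentation genes rose in 9 of 13 at 4 h and 10 at 6 h, including the peptide transporter Tap1 (2.27 ± 0.29 at 6 h). Each of these lists passed camera at 6 h, with adjusted p with an estimated correlation of 1.40e-04, 0.00894, 1.75e-04, 2.07e-05, 2.16e-05 and 0.0211. Adjusted over the list alone, the members higher at 6 h numbered 30, 11, 9, 32, 20 and 11.

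In Ctrl, cell cycle genes fell in 9 of 23 at 6 h and 1 rose (adjusted p = 4.28e-04, and 0.0281 with an estimated correlation), with the replication helicase subunit Mcm3 at −3.51 ± 0.45. Bhlhe41, a circadian repressor, changed by −7.62 ± 0.78 at 6 h, to a level under the floor of 3 counts. Glycolysis and HIF1A targets rose in 7 of 20 at 6 h, among them Hif1a itself (3.50 ± 0.29), with an adjusted p of 8.48e-04 and of 0.0657 with an estimated correlation. Altogether 434, 1303, 2594 and 2826 genes were called at 1, 2, 4 and 6 h, of which 389, 973, 1572 and 1626 rose. The split at 4 and 6 h turned with the scaling: by the genes with a mean of at least 32 CPM 1198 rose and 1795 fell at 4 h and 1271 and 1807 at 6 h, with the median of all log2 fold changes moved by −0.341 and −0.299, and by −0.178 at 2 h. These counts shrink when 1 library is left out. Without Ctrl 0 h replicate 1 or replicate 2 268 or 255 genes were called at 1 h and 800 or 775 at 2 h, and without Ctrl 2 h replicate 1 or 2 the count at 2 h was 841 or 835. At 4 h the count was 1677 without Ctrl 0 h replicate 2, 1698 without Ctrl 4 h replicate 1 and 1619 without replicate 2, and at 6 h it was 1822 without Ctrl 0 h replicate 2 and 1818 without Ctrl 6 h replicate 1.

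The second comparison asks what DI had done to the cells before the stimulus, at 0 h. Targets of NRF2, the transcription factor of the oxidative and electrophile stress response, were far higher in DI. The cystine transporter gene Slc7a11 was at 68.0 ± 2.65 against 2.13 ± 0.158 CPM (log2 fold change 4.98 ± 0.35, adjusted p = 1.32e-09, n = 2 per group). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose by 3.58 ± 0.31, and Hmox1, heme oxygenase 1, was at 212 ± 26.9 against 23.4 ± 6.40 CPM (3.18 ± 0.33). Nqo1, a quinone reductase, rose by 4.34 ± 0.56, and the glutathione transferase Gsta3 by 6.23 ± 0.74. Of the 32 NRF2 targets 26 were higher, 0 lower and 6 not called (30 higher adjusted over the list alone), with a median log2 fold change of 2.15 and an adjusted p of 5.90e-51.

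Interferon-stimulated genes were lower in DI before any stimulus. Of 32 type I interferon-stimulated genes 9 were lower and 0 higher (15 lower adjusted over the list alone), with a median of −0.68 and an adjusted p of 5.84e-11, 3.93e-04 with an estimated correlation. Mx1, an antiviral GTPase, was at 75.8 ± 7.44 against 269 ± 49.1 CPM (−1.83 ± 0.27), and Cxcl10, a chemokine for T cells, at 18.9 ± 0.490 against 65.2 ± 0.853 CPM (−1.78 ± 0.26). IFNg-induced GTPases and regulators were lower in 5 of 20 (10 adjusted over the list alone), including Iigp1 (−2.55 ± 0.29) and the costimulatory receptor Cd40 (−2.40 ± 0.41). Their median was −1.09, or −0.68 with the members at 0 in both libraries of a group set to the bound that 3 counts allow, and their adjusted p was 3.94e-07. Falls outside these lists included Fgl2 (−4.04 ± 0.31), a secreted immune regulator, the chemokine Ccl7 (−3.21 ± 0.28) and Zfp36l1 (−3.30 ± 0.30), an mRNA decay factor. Nfkbiz was at 4.32 ± 0.396 against 35.5 ± 0.165 CPM (−3.04 ± 0.30, adjusted p = 2.51e-07).

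Early response genes went both ways at 0 h. NF-kB primary response genes were higher in 5 and lower in 5 of 32 (7 and 6 adjusted over the list alone), with Cxcl3 (3.10 ± 0.57) and Tnfaip2 (1.57 ± 0.29) among those higher, and the list did not pass (adjusted p = 0.788). Its median was 0.04, its mean −0.31 and its test direction up. Of 17 immediate-early genes 4 were higher, including the AP-1 subunit Fosl1 (4.71 ± 0.86) and the phosphatase Dusp1 (1.55 ± 0.30), and 1 lower (7 and 3 adjusted over the list alone, adjusted p = 0.211, median −0.20, mean 0.29, test direction up). The glucose transporter Slc2a1 was 1.70 ± 0.30 higher, and the glycolysis and HIF1A targets had 3 of 20 higher and 0 lower (5 adjusted over the list alone, adjusted p = 4.38e-05, 0.0336 with an estimated correlation). Activated macrophage effector genes were higher in 1 and lower in 3 of 16 (9 lower adjusted over the list alone, adjusted p = 8.56e-04, 0.0333 with an estimated correlation), with the receptor Fpr2 at −1.42 ± 0.35. Of 23 cell cycle genes 1, Mcm3 (−1.62 ± 0.39), was lower (4 adjusted over the list alone, adjusted p = 1.41e-04, 0.0268 with an estimated correlation).

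In all, 384 genes were called at 0 h, 153 higher and 231 lower in DI. Far fewer were called with only the groups compared and more with the DESeq2 Wald test, as given below. Without Ctrl 0 h replicate 1 or replicate 2 the count was 186 or 188. The calls of Cd40, Dusp1, Fosl1, Fpr2 and Mcm3 were lost without one or other of the 0 h libraries, and those of Cd40, Cxcl3, Dusp1, Fpr2 and Mcm3 with only the groups compared in the model. That of Cxcl3 was also lost in limma-voom and that of Cd40 with quality weights. In this and each later treatment comparison the DI libraries are also those of low complexity, so the groups compared differ in both. With Ctrl reads thinned to the estimated molecules of DI the counts at 0, 1, 2, 4 and 6 h were 252, 336, 401, 658 and 1040 (medians of 5 draws), and thinned to the share of genes at 0 in DI 304, 405, 484, 751 and 1227.

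At 1 h the third comparison asks how DI changed the early response. The early response genes Tnf, Egr1 and Nfkbiz were lower in DI. Tnf was at 187 ± 4.14 against 730 ± 123 CPM (−1.96 ± 0.27, adjusted p = 2.65e-05), Egr1 at 78.9 ± 0.935 against 544 ± 56.1 CPM (−2.79 ± 0.34) and Nfkbiz at 650 ± 161 against 2486 ± 40.4 CPM (−1.94 ± 0.26). Il1b, the interleukin 1 beta gene, was at −4.99 ± 0.39, Il12b at −6.56 ± 0.58 and Tnfsf9, the 4-1BB ligand, at 3.88 ± 0.759 against 376 ± 189 CPM (−6.61 ± 0.53). Acod1 and Cxcl10 were not called, with log2 fold changes of −0.14 ± 0.29 and −0.19 ± 0.24.

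Of the 32 NF-kB primary response genes 20 were lower and 1 higher at 1 h (23 and 1 adjusted over the list alone). Their median was −1.65 and their adjusted p 5.08e-20, 0.00160 with an estimated correlation, with the adhesion molecule Icam1 at −2.19 ± 0.25 and the chemokine receptor-like Ccrl2 at −2.38 ± 0.28. Immediate-early genes were lower in 8 of 17 and higher in none (13 lower and 1 higher adjusted over the list alone, median −1.40, adjusted p = 1.27e-08), among them Ier2 (−4.03 ± 0.49) and the phosphatase Dusp2 (−4.78 ± 0.57). Of 9 IkBz-dependent genes 3 were lower (4 adjusted over the list alone, adjusted p = 7.01e-06), with Il6 at 1.96 ± 0.781 against 30.4 ± 3.25 CPM (−3.90 ± 0.45). Their median was −0.91, or −0.88 with bounds for members at 0. At this time type I interferon-stimulated genes were lower in 12 of 32 (20 adjusted over the list alone, median −0.83, adjusted p = 1.38e-11), and IFNg-induced genes in 4 of 20 (11 adjusted over the list alone, adjusted p = 2.17e-06), with Mx1 at −1.96 ± 0.27 and Cd40 at −2.46 ± 0.37.

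NRF2 targets stayed higher at 1 h in 24 of 32 (29 adjusted over the list alone, median 1.63, adjusted p = 2.50e-36), with Gclc, the catalytic subunit of glutathione synthesis, at 1022 ± 430 against 78.1 ± 5.44 CPM (3.71 ± 0.33). Slc7a11 was 1.17 ± 0.28 higher and Hmox1 2.93 ± 0.33. Effector genes were lower in 5 of 16 (10 adjusted over the list alone, adjusted p = 1.78e-06), with Nos2 at −3.69 ± 0.60. Macrophage identity genes were lower in 4 of 16 (8 adjusted over the list alone, adjusted p = 2.63e-05, 0.0268 with an estimated correlation), among them Cd14, the LPS co-receptor (−2.42 ± 0.39). Cell cycle genes were lower in 3 of 23 (5 adjusted over the list alone, adjusted p = 7.20e-06, 0.0113 with an estimated correlation). In all, 521 genes were called, 198 higher and 323 lower. The count was 254 without Ctrl 1 h replicate 1, 271 without Ctrl 1 h replicate 2 and 252 without DI 1 h replicate 2. The call of Slc7a11 was lost without any 1 of the 4 libraries at 1 h, and that of Nos2 in limma-voom with and without quality weights.

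At 2 h Tnf no longer differed by the test, while Il12b and Il6 stayed lower in DI. Tnf was not called (1173 ± 137 against 1432 ± 122 CPM, log2 fold change −0.29 ± 0.26, adjusted p = 0.597). Nfkbiz was at 822 ± 90.1 against 1677 ± 24.3 CPM (−1.03 ± 0.25, adjusted p = 0.0141). Il12b, the shared subunit of interleukins 12 and 23, was at 0.645 ± 0.912 against 753 ± 20.2 CPM (−10.22 ± 0.64), and Il6 at 23.2 ± 8.76 against 152 ± 20.8 CPM (−2.71 ± 0.38). The Il12b level in DI lay under the floor of 3 counts (0.679 and 0.732 CPM), so the size of its fall is imprecise. Il1b was at −3.43 ± 0.35 and Nos2 at −3.19 ± 0.44. NF-kB primary response genes were lower in 13 and higher in 1 of 32 (16 and 1 adjusted over the list alone, median −0.73, adjusted p = 1.05e-05, 0.0473 with an estimated correlation). IkBz-dependent genes were lower in 5 of 9 (7 adjusted over the list alone, median −1.64, adjusted p = 3.69e-07), among them Edn1 (−4.62 ± 0.56), which encodes endothelin 1, and Ebi3 (−1.64 ± 0.28), a subunit of interleukin 27. Immediate-early genes were higher in 2 and lower in 2 of 17 and the list did not pass (2 and 5 adjusted over the list alone, adjusted p = 0.637).

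Of the 32 type I interferon-stimulated genes 8 were lower at 2 h (20 adjusted over the list alone, median −0.80, adjusted p = 9.81e-06), including the RNA sensor Ifih1 (−1.72 ± 0.35). Cxcl10 was not called (0.35 ± 0.24). IFNg-induced genes were lower in 6 and higher in 1 of 20 (7 and 1 adjusted over the list alone), and the call of the list, adjusted p = 0.0137, was lost at an adjusted p = 0.0673 with an estimated correlation. NRF2 targets were higher in 26 of 32 (27 higher and 1 lower adjusted over the list alone, median 1.73, adjusted p = 4.31e-33), with Gclm at 2562 ± 72.6 against 167 ± 25.5 CPM (3.94 ± 0.32). The peroxiredoxin gene Prdx1 was 3.35 ± 0.30 higher, and reads of it can be shared with pseudogenes. Effector genes were lower in 7 of 16 (9 adjusted over the list alone, adjusted p = 6.20e-04, 0.0302 with an estimated correlation), with Il27 at −2.87 ± 0.31. In all, 665 genes were called, 242 higher and 423 lower. The count was 306 without Ctrl 2 h replicate 1, 318 without Ctrl 2 h replicate 2 and 276 without DI 2 h replicate 2. Without DI 2 h replicate 2 the calls of Nfkbiz, Ifih1 and Nupr1 were lost, and that of Nfkbiz also without either Ctrl 2 h library and with only the groups compared. The calls of Nfkbiz and Ifih1 were lost without the 3 DI libraries with the most genes at 0 as well.

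At 4 h Il12b, Il6 and Il10 stood far below Ctrl in DI while Tnf did not differ by the test. Il12b was at 1.55 ± 0.809 against 1373 ± 122 CPM (−9.79 ± 0.59, adjusted p = 3.55e-10), Il6 at 25.8 ± 1.70 against 393 ± 65.3 CPM (−3.92 ± 0.40) and Il10, an anti-inflammatory cytokine gene, at 3.47 ± 1.46 against 92.9 ± 14.3 CPM (−4.74 ± 0.69). At 8.22 and 8.86 estimated reads per molecule in these DI libraries, the DI levels of Il12b and Il10 rest on few molecules. The sizes of their falls are imprecise. Nfkbiz was at 210 ± 2.97 against 965 ± 17.9 CPM (−2.20 ± 0.26, adjusted p = 4.09e-06). Tnf was at 1251 ± 386 against 1387 ± 65.3 CPM (−0.15 ± 0.26, adjusted p = 0.789), and Nos2 (−0.47 ± 0.39) and Acod1 (0.83 ± 0.29) were not called. IkBz-dependent genes were lower in 6 of 9 (8 adjusted over the list alone, median −2.89, adjusted p = 5.05e-09), with Ebi3 at −2.89 ± 0.29 and the acute-phase gene Saa3 at −2.32 ± 0.39. NF-kB primary response genes were lower in 13 and higher in 2 of 32 (17 and 2 adjusted over the list alone, median −0.71, adjusted p = 5.22e-06, 0.0408 with an estimated correlation), with the activation marker Cd83 at −2.91 ± 0.39. Immediate-early genes were lower in 7 and higher in 3 of 17 (9 and 3 adjusted over the list alone), with Ier2 at −4.98 ± 0.58 and Fos at 2.41 ± 0.49, and the call of the list, adjusted p = 0.0370, was lost at an adjusted p = 0.104 with an estimated correlation.

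The type I interferon-stimulated list was lower in 10 of 32 members at 4 h (13 adjusted over the list alone, median −0.61, adjusted p = 9.81e-06), including Isg20 (−2.21 ± 0.33) and Usp18 (−1.69 ± 0.29), while the IFNg-induced list did not pass (adjusted p = 0.0762, 4 of 20 lower, 5 lower and 1 higher adjusted over the list alone). NRF2 targets were higher in 25 of 32 (28 adjusted over the list alone, median 1.84, adjusted p = 6.92e-29), with the sulfiredoxin Srxn1 at 572 ± 98.9 against 39.1 ± 4.95 CPM (3.87 ± 0.30). Acss2, an acetyl-CoA synthetase, was 5.28 ± 0.81 higher. Effector genes were lower in 9 of 16 (11 lower and 2 higher adjusted over the list alone, adjusted p = 0.00101, 0.0336 with an estimated correlation). Macrophage identity genes were lower in 7 of 16 (7 adjusted over the list alone, adjusted p = 8.56e-04), a call lost at an adjusted p = 0.0544 with an estimated correlation, with the complement gene C1qa at −1.53 ± 0.27. Cell cycle genes were lower in 4 and higher in 1 of 23 (the same counts adjusted over the list alone, median −1.96, or −1.47 with bounds for members at 0, adjusted p = 5.54e-04, 0.0341 with an estimated correlation). In all, 1006 genes were called, 366 higher and 640 lower, a share of 36.4% higher. Scaled by the genes with a mean of at least 32 CPM, 478 were higher and 522 lower, 47.8% higher, with the median of all log2 fold changes moved by 0.112, and a refit of those genes alone gave 50.8%. The count was 476 without Ctrl 4 h replicate 1, 421 without Ctrl 4 h replicate 2 and 543 without DI 4 h replicate 2. Fos was not called without Ctrl 4 h replicate 2, and Acod1 was called in limma-voom and under the scaling by genes of at least 32 CPM.

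At 6 h Cxcl2, Cxcl1 and Tnf were higher in DI, while Il12b, Il6 and Il10 stayed lower. Cxcl2 was at 6940 ± 2502 against 821 ± 37.0 CPM (3.08 ± 0.31, adjusted p = 1.65e-07), Cxcl1 at 290 ± 13.5 against 23.1 ± 13.9 CPM (3.64 ± 0.42) and Tnf at 790 ± 102 against 307 ± 53.4 CPM (1.36 ± 0.26, adjusted p = 7.72e-04). Il12b was at 4.62 ± 1.88 against 1199 ± 433 CPM (−8.05 ± 0.53), Il6 at 28.4 ± 14.6 against 278 ± 19.2 CPM (−3.30 ± 0.39), Il10 at −6.69 ± 0.84 and Ch25h, the cholesterol 25-hydroxylase, at −6.07 ± 0.54. The DI level of Il12b again rests on few molecules, so the size of its fall is imprecise. Nfkbiz was at 135 ± 43.0 against 771 ± 96.7 CPM (−2.52 ± 0.27, adjusted p = 3.87e-07) and Nos2 at −1.62 ± 0.40. IkBz-dependent genes were lower in 5 of 9 (6 adjusted over the list alone, median −3.27, adjusted p = 7.01e-07). NF-kB primary response genes were higher in 5 and lower in 10 of 32 (5 and 16 adjusted over the list alone) and the list did not pass (adjusted p = 0.127). Nor did the immediate-early genes, 4 higher and 7 lower (4 and 9 adjusted over the list alone, adjusted p = 0.480).

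NRF2 targets were higher in 29 of 32 at 6 h (the same count adjusted over the list alone, median 2.43, adjusted p = 3.61e-30), with Gclc at 570 ± 237 against 15.0 ± 2.47 CPM (5.24 ± 0.37), Srxn1 at 5.10 ± 0.33 and Hmox1 at 120 ± 31.1 against 5.49 ± 1.85 CPM (4.46 ± 0.38). Type I interferon-stimulated genes were lower in 13 of 32 (18 adjusted over the list alone, median −0.80, adjusted p = 6.44e-06), with Usp18 at −2.05 ± 0.30 and Ifit1, whose reads can be shared with its paralogs, at −1.52 ± 0.34. IFNg-induced genes were lower in 8 of 20 (10 adjusted over the list alone, median −1.15, adjusted p = 0.00287, 0.0341 with an estimated correlation), with the transcription factor Irf8 at −1.72 ± 0.32 and the chemokine Cxcl9 at −1.63 ± 0.34. Effector genes were lower in 11 and higher in 1 of 16 (12 and 1 adjusted over the list alone, adjusted p = 5.90e-04, 0.0302 with an estimated correlation). Glycolysis and HIF1A targets were higher in 8 and lower in 3 of 20 (the same counts adjusted over the list alone), with the enzymes Pkm (1.17 ± 0.27) and Pgam1 (1.20 ± 0.30) higher and Hif1a (−1.61 ± 0.27) and the regulator Pfkfb3 (−1.88 ± 0.42) lower. The call of that list, adjusted p = 0.0163, was lost at an adjusted p = 0.166 with an estimated correlation. Bhlhe41 was at 20.6 ± 7.67 against 0.149 ± 0.211 CPM (6.80 ± 0.80). Its Ctrl level lay under the floor of 3 counts (0.821 and 0.724 CPM), so the size of this difference is imprecise. In all, 1513 genes were called, 559 higher and 954 lower, a share of 36.9% higher. Scaled as at 4 h, 702 were higher and 786 lower, 47.2% higher, with the median moved by 0.131, and the refit gave 48.0%. The count was 750 without Ctrl 6 h replicate 1 and 890 without Ctrl 6 h replicate 2. Without Ctrl 6 h replicate 1 the calls of Ifit1, Nos2, Pgam1 and Pkm were lost, and that of Ifit1 also without the 3 DI libraries with the most genes at 0.

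**Figure D2:**
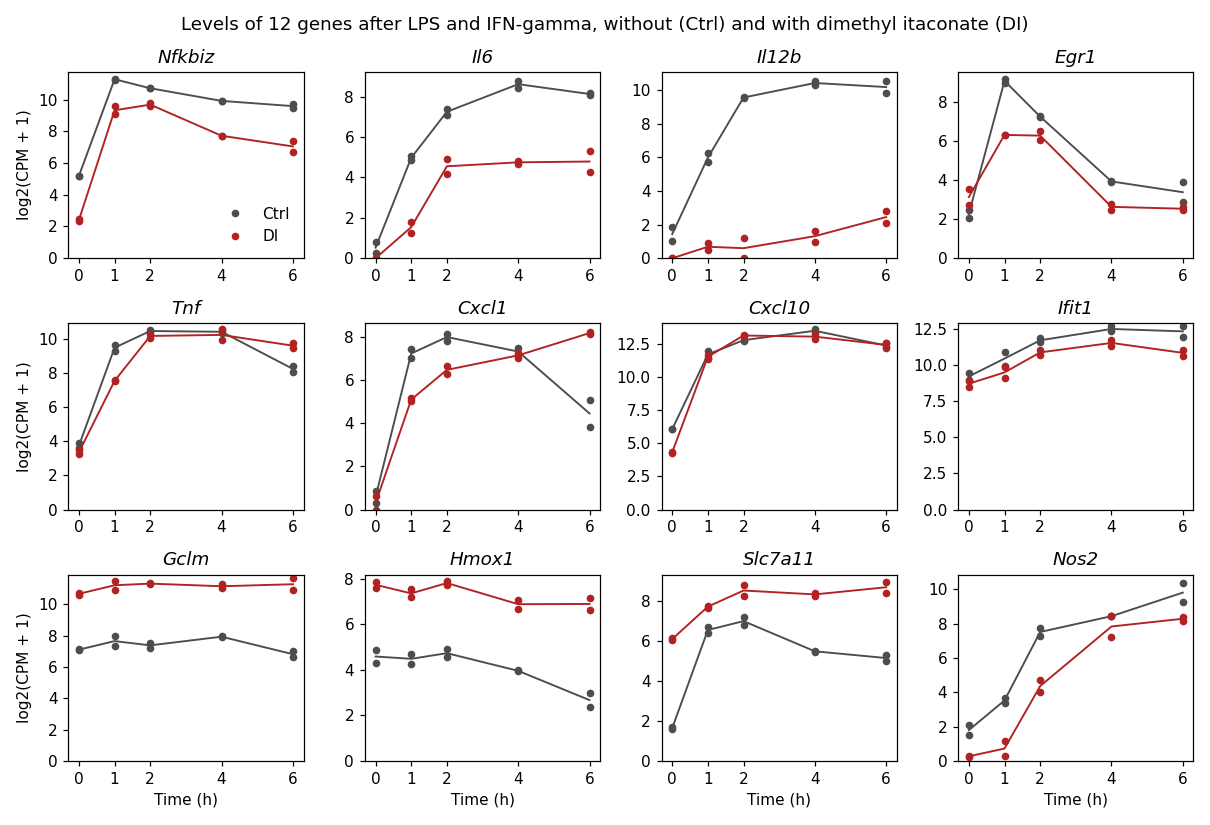
Levels of 12 named genes as log2 of CPM plus 1, by time after the stimulus in h, with 1 point per library, lines through the group means of these values and Ctrl and DI in separate colours. Tnf is lower in DI at 1 h (187 ± 4.14 against 730 ± 123 CPM) and higher at 6 h (790 ± 102 against 307 ± 53.4 CPM).

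Lists with fewer or less steady calls complete the treatment comparison. The ATF4 and integrated stress response list had adjusted p = 0.0130 at 0 h with 1 of 16 members higher and 0.0239 at 2 h with 3 higher and 2 lower, and adjusted p = 0.0931 and 0.124 with an estimated correlation. Adjusted over the list alone, 3 members were higher at 0 h and 5 at 2 h, when the kinase-like Trib3 was at 2.22 ± 0.41 and the stress gene Nupr1 at −2.25 ± 0.43. Heat shock chaperones passed at 0, 1 and 6 h (adjusted p = 0.00132, 0.0274 and 0.0302) with 0, 1 and 2 of 13 higher, and lost the call with adjusted p = 0.0931, 0.222 and 0.228 with an estimated correlation. Adjusted over the list alone, 2, 1 and 3 were higher. Glycolysis and HIF1A targets at 1, 2 and 4 h had adjusted p = 0.0199, 0.00287 and 0.0175 with 1, 4 and 4 of 20 higher, and adjusted p = 0.166, 0.0931 and 0.166 with an estimated correlation. MHC class II presentation was lower at 1 h (1 of 7, adjusted p = 3.01e-04) and 4 h (2, adjusted p = 0.0274), with adjusted p = 0.112 and 0.323 with an estimated correlation. Macrophage identity genes at 0 and 2 h had adjusted p = 0.00181 and 0.0269 with 2 and 2 of 16 lower, and adjusted p = 0.0689 and 0.166 with an estimated correlation. Cell cycle genes at 2 h had adjusted p = 0.0109, and adjusted p = 0.0931 with an estimated correlation. MHC class I presentation, cholesterol biosynthesis, mitochondrially encoded transcripts and dendritic cell markers passed at no time.

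Neutrophil and granulocyte precursor markers summed to 632 ± 55.4 CPM in Ctrl and 552 ± 14.7 in DI at 0 h, 616 ± 94.6 and 419 ± 71.1 at 1 h, and 267 ± 8.11 and 444 ± 152 at 6 h. Their list passed at 1 h with 0 of 9 members called (adjusted p = 0.0143), and had adjusted p = 0.203 with an estimated correlation. Stromal markers summed to 62.2 ± 12.4 in Ctrl and 34.6 ± 9.36 in DI at 0 h, and were lower in 2 of 5 at 4 h (3 adjusted over the list alone, adjusted p = 0.00358, 0.0469 with an estimated correlation). In Ctrl at 4 h, T cell markers summed to 16.3 ± 2.68, B cell markers to 3.12 ± 0.991, dendritic cell markers to 10.8 ± 2.79 and mast cell markers to 5.08 ± 2.21 CPM, and erythroid markers were at 0. In DI at 4 h the T cell, B cell, dendritic cell and mast cell sums were 1.60 ± 1.93, 0.635 ± 0.898, 8.35 ± 1.06 and 1.52 ± 0.845 CPM. The reference gene Actb was called at no time in DI against Ctrl, with log2 fold changes from −0.79 ± 0.30 at 6 h to −0.49 ± 0.30 at 0 h, and Gapdh, whose reads can be shared with pseudogenes, was not called either, with −1.04 ± 0.33 at 1 h and 0.48 ± 0.33 at 6 h. Limma-voom called Actb at 6 h, and the DESeq2 Wald test called Gapdh at 1 h.

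**Figure D3:**
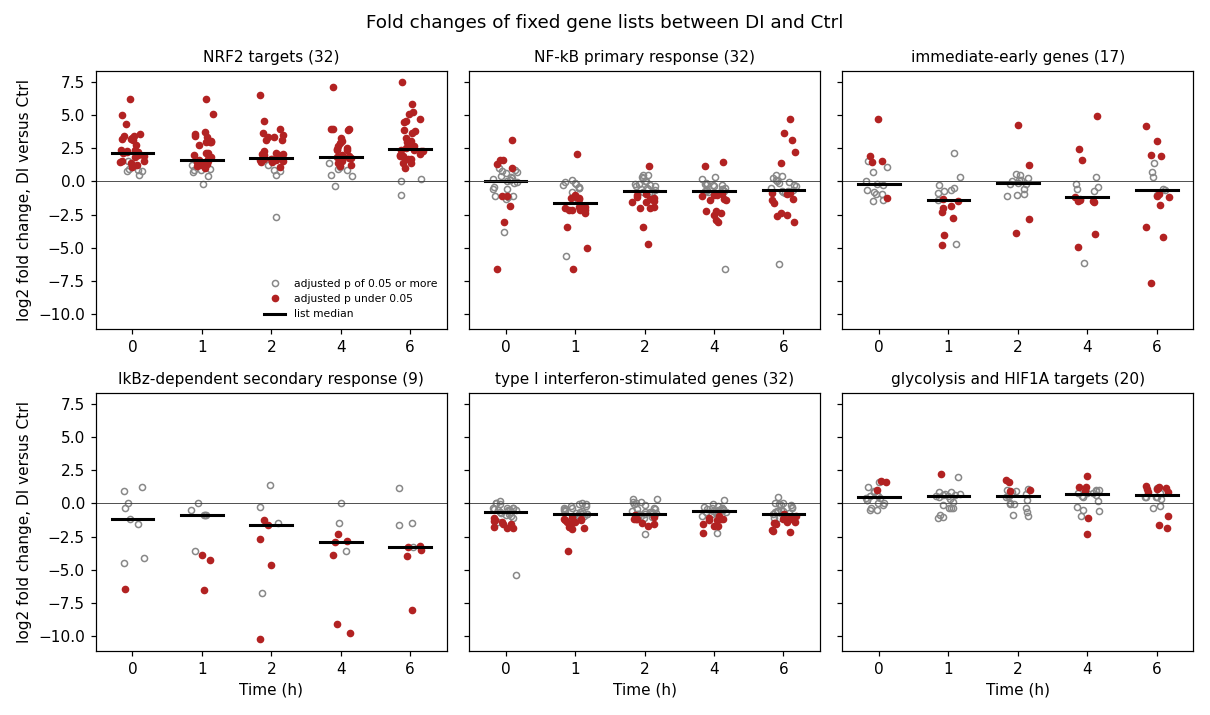
Log2 fold change of DI against Ctrl at 0, 1, 2, 4 and 6 h for the measured members of 6 fixed lists, 1 point per gene, filled where the adjusted p was under 0.05 and open where it was not. Bars are list medians, and those of NRF2 targets lie between 1.63 and 2.43, and those of type I interferon-stimulated genes between −0.83 and −0.61.

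Macrophages given DI still responded to LPS and IFNg. Against their own 0 h libraries, 22, 30, 29 and 29 of 32 NF-kB primary response genes rose at 1, 2, 4 and 6 h, with Tnf at 4.31 ± 0.31, 6.96 ± 0.34, 7.05 ± 0.34 and 6.39 ± 0.33. Nfkbiz rose by 7.24 ± 0.34 at 1 h and was 4.96 ± 0.32 above its 0 h level at 6 h. Cxcl10 rose by 8.86 ± 0.35 at 2 h, Acod1 by 8.46 ± 0.40 at 4 h and Nos2 by 10.39 ± 0.69 at 6 h. Type I interferon-stimulated genes rose in 7, 20, 24 and 26 of 32, and IFNg-induced genes in 14, 17, 18 and 18 of 20. IkBz-dependent genes rose in 1, 2, 4 and 6 of 9, and Il6 and Il12b were at 0 in both DI libraries at 0 h. Adjusted over the list alone, the members higher at 6 h numbered 30, 28, 18 and 6 in these 4 lists, and with an estimated correlation the adjusted p at 6 h was 9.59e-05, 2.03e-05, 2.03e-05 and 0.00242. In all, 383, 1170, 1998 and 2149 genes were called at 1, 2, 4 and 6 h, of which 351, 841, 1215 and 1199 rose. Fewer were called in DI with only the groups compared and with quality weights, and more in Ctrl, as given below. The counts of the Ctrl and DI responses are therefore not compared in size. Here too the split turned under the other scaling, with 988 higher and 1212 lower at 4 h and 1010 and 1260 at 6 h, and medians moved by −0.140, −0.140, −0.231 and −0.169.

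The response difference asks whether the change from 0 h differed between DI and Ctrl, which the comparisons within each treatment do not test. Of the 27 genes called at 1 h 23 had a lower response in DI. Tnfsf9 differed by −7.33 ± 0.68 (adjusted p = 1.02e-06), Egr1 by −3.86 ± 0.49, Tnfaip3, an inhibitor of NF-kB signalling, by −3.43 ± 0.49 and Cxcl2 by −2.50 ± 0.42. Slc7a11, which was already high in DI at 0 h, differed by −3.81 ± 0.43. Nfkbiz went the other way, with 1.11 ± 0.38 at 1 h, not called (adjusted p = 0.645), and 2.01 ± 0.39 at 2 h (adjusted p = 0.0118), a call lost in limma-voom with and without quality weights, in estimated molecules, with only the groups compared and without Ctrl 0 h replicate 1, DI 0 h replicate 2 or either Ctrl 2 h library. The NF-kB primary response list differed with 6 of 32 members lower at 1 h (16 lower and 1 higher adjusted over the list alone, median −1.14, adjusted p = 1.03e-28, 8.97e-04 with an estimated correlation), and the immediate-early list with 4 of 17 lower (8 adjusted over the list alone, median −1.83, adjusted p = 1.65e-16, 4.91e-04 with an estimated correlation). At 2 and 4 h the NF-kB list had adjusted p = 8.69e-06 and 3.92e-06 with 5 and 5 members lower, and adjusted p = 0.107 and 0.0991 with an estimated correlation. At 6 h it did not pass (adjusted p = 0.447).

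Later differences included Ebi3 at −3.23 ± 0.39 and Il10 at −4.86 ± 1.15 at 6 h. More positive responses in DI were found at 6 h for Cxcl1 (4.78 ± 1.01), Tnf (1.77 ± 0.39), Cxcl10 (1.82 ± 0.36) and Bhlhe41 (7.14 ± 0.94), and at 4 h for Iigp1 (2.43 ± 0.39) and Plau, the urokinase gene (2.75 ± 0.57). Cxcl10 and Iigp1, like Nfkbiz, had started lower in DI at 0 h. IkBz-dependent genes differed at 1, 2, 4 and 6 h (adjusted p = 1.36e-05, 7.03e-08, 3.33e-10 and 5.58e-08, medians −0.13, −0.97, −2.01 and −1.62) with 0, 0, 1 and 2 of 9 members called lower (0, 1, 2 and 2 adjusted over the list alone), and Il6, Il12b, Il12a and Edn1 were at 0 in DI at 0 h, so their fitted responses are not bounded by counts. The response of type I interferon-stimulated genes did not differ by the test, with medians of −0.07, 0.08, 0.02 and −0.02 and adjusted p = 0.573, 0.361, 0.594 and 0.979. In all, 27, 38, 81 and 165 genes were called at 1, 2, 4 and 6 h, of which 23, 26, 61 and 104 were lower. Under that scaling the medians at 4 and 6 h moved by 0.110 and 0.129, and 51 and 92 of 78 and 173 called genes were lower. The count at 1 h was 16 without Ctrl 0 h replicate 1 and 14 without Ctrl 1 h replicate 1. At 2 h it was 19 and 24 without Ctrl 0 h replicate 1 and 2, 25 without Ctrl 2 h replicate 2 and 60 without DI 2 h replicate 1. At 4 h it was 44 and 37 without Ctrl 0 h replicate 1 and 2, 47 and 39 without Ctrl 4 h replicate 1 and 2, and 141 and 46 without DI 4 h replicate 1 and 2. At 6 h it was 90 and 61 without Ctrl 0 h replicate 1 and 2, 69 and 79 without Ctrl 6 h replicate 1 and 2, and 99 without DI 6 h replicate 2. The calls of Cxcl1, Il10 and Tnf at 6 h and of Plau at 4 h were lost without Ctrl 0 h replicate 2 and with only the groups compared, those of Cxcl1, Il10 and Tnf also in limma-voom with and without quality weights, those of Cxcl1 and Il10 in estimated molecules, that of Plau without the 3 DI libraries, and that of Cxcl10 at 6 h without Ctrl 6 h replicate 1.

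The series title places the action of DI on a secondary wave of NF-kB signalling, so induced genes were split by when they rose in Ctrl. Both early and late induced genes, as defined in Ctrl, were lower in DI. No class was defined in DI, and genes with a larger response in Ctrl enter the classes more readily. A weaker response of these classes in DI is therefore partly built in, although no library is shared. The early class was not tested at 1 h, so these tests do not separate an early from a late action of DI. Of 380 early induced genes 118 were lower and 12 higher at 2 h (median −0.67), 134 and 12 at 4 h (−0.71), and 158 and 37 at 6 h (−0.81). Of 1180 late induced genes 151 were lower and 19 higher at 2 h (−0.42), and 286 and 24 at 4 h (−0.69), and of 1109 at 6 h 392 were lower and 45 higher (−0.79). Each of these 6 tests passed, with adjusted p from 2.43e-16 to 6.17e-08 and from 2.61e-05 to 0.00146 with an estimated correlation. Late repressed genes were higher in DI more often than lower, with 60 higher and 40 lower of 1110 at 2 h, 106 and 22 at 4 h, and 133 and 26 of 940 at 6 h (adjusted p = 0.0432, 1.22e-07 and 1.22e-07). The call at 2 h was lost with size factors of DESeq2 (adjusted p = 0.0555), in estimated molecules (0.244), at a class limit of 2 (0.466), and without Ctrl 2 h replicate 2 (0.0836) or DI 2 h replicate 1 (0.103). Early repressed genes, 45 in number, had 2 higher and 2 lower at 2 h (adjusted p = 0.0137, and adjusted p = 0.0551 with an estimated correlation), 6 higher and 2 lower at 4 h (adjusted p = 0.00282), and no call at 6 h (adjusted p = 0.139). Their call at 2 h was also lost in estimated molecules (adjusted p = 0.184) and without the libraries just named (0.0836 and 0.103), and their calls at 2 and 4 h at a class limit of 2 (0.124). An exact permutation test of 2 against 2 libraries can give no p under 1/3, so none is given.

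In GRCm38 coordinates, genes followed through these comparisons are Nfkbiz (ENSMUSG00000035356, chromosome 16, 55811375 to 55838899), Il12b (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), Gclm (ENSMUSG00000028124, chromosome 3, 122245557 to 122270732), Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) and Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), all protein coding.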

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

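In this part the comparisons of responses between DI and Ctrl were planned, while the tests that weigh explanations and the comparison of the treatment effect at 6 h with that at 1 h were chosen only after the results were seen. What stands out is that the response to LPS and IFNg differed between the treatments. It did so for 27 genes at 1 h, 38 at 2 h, 81 at 4 h and 165 at 6 h, counts that vary with the processing as given below. At 1 h the response of Tnfsf9 was lower in DI (−7.33), as were those of Egr1 (−3.86), Tnfaip3 (−3.43), Cxcl2 (−2.50) and Slc7a11 (−3.81). At 2 h the response of Nfkbiz was higher in DI (2.01), a call lost under several alternatives, although its level stayed below that of Ctrl at each time. At 4 h the responses of Iigp1 (2.43), which started lower in DI at 0 h, and Plau (2.75) were higher. At 6 h Ebi3 (−3.23) and Il10 (−4.86) were lower, and Cxcl1 (4.78), Tnf (1.77), Cxcl10 (1.82) and Bhlhe41 (7.14) higher. Cxcl10 had also started lower in DI at 0 h. The calls of Plau, Cxcl1, Il10, Tnf and Cxcl10 were each lost under alternatives given in the Results.

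Among the lists, the NF-kB primary response differed with a median of −1.14 at 1 h, −0.44 at 2 h and −0.84 at 4 h, with adjusted p = 0.107 and 0.0991 with an estimated correlation at 2 and 4 h. Immediate-early genes differed with −1.83 at 1 h and −0.73 at 4 h, the latter at an adjusted p of 0.00145. IkBz-dependent genes differed with −0.13, −0.97, −2.01 and −1.62 at 1, 2, 4 and 6 h. MHC class II presentation differed at 1 h (median −0.66, adjusted p = 0.00583, and adjusted p = 0.353 with an estimated correlation). IFNg-induced genes differed at 4 h (median 0.60, adjusted p = 0.0374, and adjusted p = 0.177 with an estimated correlation), as did stromal markers (−0.30, 0.0370, and adjusted p = 0.193 with an estimated correlation). At 6 h NRF2 targets (0.35, adjusted p = 0.0303) and cell cycle genes (0.85, adjusted p = 0.0374) differed, with adjusted p = 0.453 and 0.239 with an estimated correlation. The effect of DI itself differed between 6 h and 1 h for 224 genes.

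More genes were lower than higher in DI at each time, with 36.4 to 39.8% of calls higher. Among the 1447 genes of highest mean level the share reached at most 36.2%, with an exact upper limit of 43.8% that takes genes as independent. This argues against low complexity of the DI libraries, acting through genes with few reads, as the whole cause. These genes kept the main scaling, so low complexity acting through the scaling was not tested by them. Of 10360 unchanged simulated genes 1 was called higher and 24 lower in DI at 4 h. Thinning Ctrl reads moved the share over all genes. Thinned to match the share of genes at 0 in DI it was 45.3% at 4 h and 42.8% at 6 h, and thinned to the estimated molecules of DI, which left 38.9 to 39.1% of genes at 0 in Ctrl against 23.9% in DI, 51.4 and 49.8%. At 2 h factors from the genes with a mean of at least 32 CPM moved the fold changes up by 0.0404 and the share to 40.0% (exact upper limit 43.9%). A refit of those genes alone gave 42.2%. These values argue only against a scaling error of that size at 2 h, and larger shifts were not tried there. At 0 and 1 h no other scaling moved the median log2 fold change up by more than 0.00198, so scaling of the libraries stays open there. It stays open at 4 and 6 h as well. There the size factors of DESeq2 alone gave 36.4 and 35.8%, but hardly moved the log2 fold changes. The factors from genes of at least 32 CPM, with genes and model kept, gave 47.8% at 4 h (exact upper limit 50.9%) and 47.2% at 6 h (49.8%). Preparation of the libraries that differed between treatments cannot be told apart from DI, since 0 of 10 DI libraries had reads per molecule within the range of Ctrl. An action of DI on the cells, the explanation the design offers, therefore stays open beside it.

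NF-kB primary response genes were lower in DI at 1 h, with a median of −1.65. Low complexity is argued against by the 29 members with a mean of at least 32 CPM, whose median was −1.47 and upper quartile −0.53. A slower response is a candidate explanation on the side of biology. Of 30 members induced in both treatments 46.7% had their highest level at a later time in DI, against 25.3% of 336 early induced genes, which neither reaches the 50% set for it nor falls under the 30% set against it.

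Type I interferon-stimulated genes were lower in DI at each of the 5 times. Scaling, which moves all genes alike, is argued against, since the list median minus the median of all genes was at most −0.544 at any time, and the upper quartile of the list minus that median at most −0.334. Low complexity is argued against too, since the median of the 31 members with a mean of at least 32 CPM was at most −0.59. A lower level before the stimulus that carried through may account for the later list medians, which differed from that at 0 h by at most 0.147. Medians do not show that the same members carried it, and the response of Cxcl10 at 6 h differed by 1.82. Between 1 and 6 h the effect of DI changed by the test for 1 of 32 members. What lowered these genes at 0 h was not tested, and DI and library preparation remain confounded there.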

How the results depend on the processing

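The alternatives were planned except for estimated molecules, quality weights, the refit at 32 CPM, the scaling by those genes and the fit without 3 DI libraries, which are tests chosen after seeing the data. With only the groups compared in the model, DI against Ctrl gave 91 genes at 0 h and 342 at 2 h, Ctrl 824, 2746, 4828 and 4630 and DI 161, 532, 926 and 1004 at 1, 2, 4 and 6 h, and the response difference 13, 8, 39 and 62. Quality weights by treatment gave 1238, 3164, 4663 and 4558 in Ctrl, 182, 614, 1055 and 1139 in DI, and 14, 53 and 109 for the response difference at 1, 4 and 6 h. The main fit shares 1 estimate of spread, while the coefficient of variation on reads was 20.2% in Ctrl and 43.8% in DI. Without the shared spread the response counts rose in Ctrl and fell in DI, the directions that such sharing would give. The main counts of the Ctrl and DI responses therefore cannot be set against each other as sizes of response. The DESeq2 Wald test gave 607, 803 and 1063 for DI against Ctrl at 0, 1 and 2 h and 50, 124, 217 and 335 for the response difference, and the cause was not tested. With no filter the response difference gave 60, 111, 183 and 273, and limma-voom gave 15 at 1 h. Estimated molecules gave 844 and 2436 in Ctrl at 1 and 2 h. Without replicate 2 of DI at 2, 4 and 6 h, the libraries with the most genes at 0, DI against Ctrl gave 621 at 0 h and 813 at 1 h, and the cause was not tested. The refit at 32 CPM, which tests fewer genes, gave 1720 and 1789 in Ctrl and 1220 and 1367 in DI at 4 and 6 h. Scaling all genes by those of at least 32 CPM left the counts of called genes within 1.5 times, but turned the split of the responses at 4 and 6 h, with 40.0 and 41.3% of calls higher in Ctrl and 44.9 and 44.5% in DI. Leaving out 1 library gave 186 to 309, 252 to 484, 276 to 705, 421 to 975 and 750 to 1322 for DI against Ctrl, 255 to 316, 775 to 841, 1619 to 1744 and 1818 to 1947 in Ctrl, and 14 to 28, 19 to 60, 37 to 141 and 61 to 197 for the response difference. Of the 95 list tests 50 passed, 32 with an estimated correlation, 51 with size factors and 46 of 85 in estimated molecules. Of the 76 list tests of the response difference 14 passed and 7 with an estimated correlation. A replicate block gave 51 and 14. Of the classes 11 of 12 passed, and 8 to 11 under the alternatives. No list call changed direction. Of 149 gene results named in these texts 137 were called, 115 of them with every single library left out and 113 under every setting with a value. With only the groups compared 12 were lost, in limma-voom 6, with quality weights 6, without the 3 DI libraries 6, in estimated molecules 3 and under the scaling by genes of at least 32 CPM 2. None changed direction.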

Other observations

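The genes named in this part and the tests reported in it were chosen after their values were seen. Calls of DI against Ctrl at the 5 times share the treatment, the library complexity that goes with it and the estimate of spread. They could not be independent, so the numbers expected under independence are given for scale and are no test. A common set of genes was higher in DI at all 5 times, 72 in number against 0.000116 if the calls were independent of each other. Beyond the fixed list of NRF2 targets they include Ednrb (4.58 ± 0.32 at 0 h), which encodes an endothelin receptor, the proteinase inhibitor Serpinb9b (4.85 ± 0.53), the glutathione synthetase Gss (3.48 ± 0.46 at 1 h), the prostaglandin reductase Ptgr1 (4.36 ± 0.41), the carbonyl reductase Cbr3 (5.45 ± 0.66 at 6 h), the transporter Slc22a4 (5.24 ± 0.53), and Mmp12, the macrophage elastase (2.03 ± 0.28). Another 65 were lower at all 5 times, against 0.00149. They include Il12b, Il1b and Nfkbiz, the NF-kB subunit Rel (−2.22 ± 0.27 at 6 h), the repressor Bcl6 (−1.87 ± 0.26), the chemokine receptor Ccr2 (−2.78 ± 0.27), the kinase Ikbke (−0.98 ± 0.31), the receptors Tlr7 (−2.72 ± 0.39) and Tlr1 (−1.15 ± 0.39), and Tmem173, which encodes the DNA sensor adaptor STING (−1.77 ± 0.38). Il12b and Il1b were at 0 in both DI libraries at 0 h, so their calls at that time depend on library complexity. With Ctrl thinned to the estimated molecules of DI, 0 IkBz-dependent genes, the list that holds Il12b, were lower at 0 h. Thinned to the share of genes at 0, 1 was lower (medians of 5 draws). The calls of Ikbke and Tlr1 at 6 h were lost without Ctrl 6 h replicate 1, Ctrl 6 h replicate 2 or DI 6 h replicate 2, under the scaling by genes with a mean of at least 32 CPM, and without the 3 DI libraries with the most genes at 0, and that of Tlr1 with only the groups compared.

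Much of the response was shared. Of the genes that rose in Ctrl, 59.9% also rose in DI at 1 h (233 genes against 12.8 if independent), 64% at 2 h (623 against 76.7), 62.3% at 4 h (979 against 179) and 58.7% at 6 h (955 against 183). Of the genes that fell in Ctrl, 17.8, 33.0, 39.4 and 44.3% also fell in DI at these times. The 2 sets of calls share no library, but they share the estimate of spread.

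The effect of DI on some NF-kB primary response genes changed with time. Between 1 and 6 h it became more positive for 12 of 32 members and more negative for 0, with Cxcl1 at 5.82 ± 0.57 (adjusted p = 1.98e-06) and Tnf at 3.33 ± 0.38 (adjusted p = 1.73e-05). Over all genes 84 became more positive and 140 more negative. Fos, Tnf, Cxcl1, Egr2 and Cxcl2 were lower in DI at 1 h and higher at 6 h, and Dip2b, Relch, Il4ra and Ext1 the reverse, 5 and 4 genes against 16.9 and 17.7 if the calls were independent. Of 30 NF-kB primary response genes induced in both treatments 14 had their highest mean level at a later time in DI, 9 at the same time and 7 earlier, those later including Il1a, Ptgs2, Icam1, Cxcl1 and Nfkbiz. Of 1284 induced genes 274 peaked later, 651 at the same time and 359 earlier.

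Some transcripts differed between replicates of a group. B2m, the light chain of MHC class I, was at 17080 ± 13090 CPM in Ctrl at 4 h, and H2-T23, an MHC class I gene with close paralogs, at 5.67 ± 5.02 CPM in DI at 0 h. Thinned to 1020000 molecules per library, which matches the share of genes at 0 in DI, DI against Ctrl still gave 0 higher and 20 lower NF-kB primary response genes at 1 h (median −1.62).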
